A study of Arabidopsis thaliana with 4 samples.

How the data were processed

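Ovules with placenta were dissected from floral buds of wild type and spl plants, and libraries were built from 6 µg of total RNA with a 3′ tag digital gene expression kit, per the labels' protocols. Plants grew under 16 h light and 8 h dark at 22 °C. Such a kit anchors transcripts at their 3′ end, cuts at CATG and sequences a short tag at the cut site, so a count reflects the number of tags and not transcript length. There were 2 libraries per genotype, named by the replicate numbers of their titles.

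The authors deposited, for each library, the raw count of tags per transcript model, together with the tags behind it. They also deposited TPM values, which here are tags per 1000000 clean tags of the library, not a transcript-based TPM; these were used only to check the counts. Per the texts deposited with the samples, tags with uncalled bases, adaptor tags and single-copy tags had been removed, and the rest had been assigned with at most 1 mismatch. The tag statistics deposited by the authors list 41671 reference transcript models, of which 38815 have a CATG site, and 76.0% of the reference tags fit a single model. The build is TAIR10 per the submitters' processing notes, and the aligner is not given in the sources used here. Only sense tags that fit a single transcript model were counted, so genes whose tags are shared between isoforms or paralogs can lack a row: 14920 of 27550 protein-coding loci of the reference had one. The smallest count listed is 2, so an absent model was set to 0, which means no tag with 2 or more copies. Clean tags numbered 5918647, 5859009, 5665231 and 6015510 in wild type 1, wild type 2, spl 1 and spl 2, and 51.1%, 51.9%, 51.8% and 48.8% of them were counted. A floor of 3 counts, used where a genotype was at 0, and all counts cover counting error only, since tags without molecular identifiers are not independent molecules. The chi-square per degree of freedom was 18.1 between the wild type and 47.1 between the spl libraries, so neither pair looked like copies of 1 library; this does not show that they came from separate plants.

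The reference used for gene names and the SPL tag was TAIR10.1, a reissue of TAIR10. Of 16083 models on chromosomes 1 to 5, 94.6% had their most abundant tag on the sense strand within the deposited coordinates. The counts were tested as deposited, per transcript model. Models were kept by edgeR's filterByExpr (11235 of 16147), scaled by TMM and tested with edgeR 4.0.16 by the quasi-likelihood F-test on genotype, in R 4.3.3, with 2 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM values use the TMM-scaled library sizes, and the standard error of a log2 fold change is its size divided by the square root of F. Lists and families were tested with camera at a correlation of 0.01, with an estimated correlation and with fry (limma 3.58.1), for lists of at least 5 and families of at least 10 tested models, adjusted over the 12 lists or the 12 families that qualified. The 15 gene lists and the 16 description patterns were fixed before the data were examined, as were the test, the other settings and the rule for named genes. The lists cover germ line specification, meiosis, ovule development, auxin, cytokinin, TCP and TOPLESS genes, tapetum and anther, mature pollen, female gametophyte, cell cycle, photosynthesis, perianth and stamen identity, carpel and transmitting tract, stress and wounding, and flavonoids; 249 of their 363 members had a row. Symbol and locus code were matched to the reference: 352 matched, 8 were taken by code, 2 codes were replaced and 1 member was dropped.

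The rule named SPL, then up to 8 models in each direction past the threshold with non-overlapping genotypes and a mean count of at least 20, and up to 4 members of each list or family past it, or otherwise the member with the smallest p. Since no model passed, SPL and the smallest-p members were named; AGO9, ANT, BEL1, INO, PIN1 and VGD1 and the 15 models called with replicate number in the fit were chosen after their values were seen. The other settings were DESeq2 size factors, library totals and upper quartile scaling, DESeq2 1.42.0, limma-trend with a prior count of 2, no low-count filter, a filter of 5 CPM in at least 2 libraries, robust dispersion, replicate number as a block, each library left out, organellar genes left out, and a log2 fold change of at least 1. Further settings, chosen after seeing the data, are named in the closing section. The enrichment test planned for gene ontology terms needs called genes and was not run; camera over 428 terms, chosen instead after seeing the data, called 0. The fits were tested on simulated counts with the means and library sizes of these libraries, their common dispersion and 200 changed genes: 86 of the 200 and 3 unchanged genes were called. Analyses of the tags used Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1.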

Results

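Transcripts of dissected ovules with their placenta were profiled in Arabidopsis thaliana of the Columbia background, from floral buds at stages 10 to 11. Wild type plants were compared with plants carrying the spl mutation, which inactivates SPOROCYTELESS (SPL, also called NOZZLE), a gene required for the first cells of the germ line in ovules and anthers. There were 2 libraries per genotype. Each library held short tags that start at CATG sites near the 3′ end of transcripts, and the analysed value was the number of tags that fit a single transcript model. These counts summed to 3023607 and 3041852 in wild type replicates 1 and 2, and to 2934515 and 2934702 in spl replicates 1 and 2. Between 13643 and 14228 transcript models were listed per library. The labels give replicate numbers but do not say that replicates were separate plants, so p-values measure only the spread between these samples, which may be technical.

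SPL itself (AT4G27330.1) was read first. Its transcript model lies on chromosome 4 from 13682078 to 13683538, on the reverse strand of TAIR10. One tag sequence, CATGGAAGGAAACCCTAGAAA, gave every SPL count. It matched the TAIR10.1 reference once, at 13682460 to 13682480 on chromosome 4, in the coding part of exon 3 of 3. The tag was counted 23 and 20 times in wild type replicates 1 and 2, and 0 and 7 times in spl replicates 1 and 2. Mean levels were 6.94 ± 0.437 counts per 1000000 (CPM) in wild type and 1.24 ± 1.75 CPM in spl (SD, n = 2). The fitted log2 fold change was -2.46 with a standard error of 1.07, and it did not pass the test over all models (edgeR quasi-likelihood adjusted p = 0.99999, unadjusted p = 0.0446). Neither the type nor the position of the lesion is given in the sources used here, so a tag outside it would not test the genotype. Both spl libraries lay below both wild type libraries.

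The first question was which genes differ between spl and wild type ovules. In the planned comparison 0 of 11235 transcript models passed an adjusted p of 0.05 with edgeR, so none was called higher or lower. At an unadjusted p under 0.05 there were 294 models, against 561.75 with uniform p-values. DESeq2 called 2 models and limma-trend 0. The 2 models were MTM1 (AT4G27940.1), a mitochondrial carrier family gene named for manganese supply to superoxide dismutase, and AT1G30795, a glycine-rich protein gene. MTM1 was counted 166 and 125 times in wild type and 15 and 10 times in spl, a log2 fold change of -3.41 (SE 0.514) with the smallest adjusted p of the edgeR comparison, 0.588. AT1G30795 was counted 8 and 6 times in wild type and 420 and 52 times in spl. A gap between the spl replicates went with this result: 549 models were over 4-fold apart between them, against 155 between the wild type replicates. The spread between libraries corresponded to a coefficient of variation of 38.1%. Without spl replicate 1 the count of called models was 95, and without spl replicate 2 it was 25.

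The libraries also split by replicate number on a technical measure. Among distinct raw tags, 0.452% and 0.471% held an uncalled base in replicate 1 of wild type and spl, and 1.64% and 1.71% in replicate 2. The share of counts at the site nearest the 3′ end was 84.9% and 85.3% in replicate 1, and 82.4% and 81.3% in replicate 2. A fit with replicate number as a term had been planned as another setting. Reading the number as a possible batch came after these values had been seen, and fold changes were also taken within each number. The fold changes of spl over wild type within replicate 1 and within replicate 2 had a correlation across models of -0.04; models are not independent replicates. At least 2-fold higher levels in spl in both replicates were seen for 99 models, with 62.1 expected from independent replicates, and at least 2-fold lower levels for 79, with 64.0 expected. When libraries of unlike number were paired instead, 69 models were higher and 86 lower in both pairs, with 130.4 and 120.4 expected and a correlation of -0.25. All these expectations treat every model as equally likely to differ 2-fold. Models of low count vary more, so an excess over them does not by itself show an effect of genotype.

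With replicate number as a term, 15 models passed with edgeR, 10 higher and 5 lower in spl. With 1 residual degree of freedom, the p-values of this fit rest mostly on a spread shared over models, not on each gene's own. The DESeq2 test with the same term called 3 models, all among the 15. The 15 were named after their values were seen. Among the 5 lower was WUS, the homeodomain regulator of stem cells that is also expressed in the ovule nucellus. WUS was counted 46 and 104 times in wild type and 2 and 33 times in spl. With replicate number in the fit its log2 fold change was -2.45 (SE 0.586), with an edgeR adjusted p of 0.0297. In the planned fit it was -1.98 (SE 0.902), with an edgeR adjusted p of 0.99999 and an unadjusted p of 0.0522. The genotypes came close for WUS in wild type replicate 1 (14.5 CPM) and spl replicate 2 (11.7 CPM). The fold changes of WUS were -3.47 within replicate 1 and -1.51 within replicate 2. MTM1 had a log2 fold change of -3.42 (adjusted p = 7.87e-07 with edgeR), with -3.17 and -3.32 within the replicates. AT1G74010, a phosphotriesterase family gene, was counted 24 and 14 times in wild type and 0 times in both spl libraries, at least 5.80-fold lower against a floor of 3 counts per library. CYP708A1, a cytochrome P450 gene, was counted 12 and 13 times in wild type and 0 times in spl, at least 3.85-fold lower on the same floor. AT2G21185, which encodes an unknown protein, was counted 30 and 26 times in wild type and 0 and 4 times in spl.

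The 10 models higher in spl with replicate number in the fit encoded proteins of several families. AT1G44970, a peroxidase, was counted 4 and 0 times in wild type and 372 and 14 times in spl (log2 fold change 6.65, SE 0.804, edgeR adjusted p = 1.63e-12). AT5G49180, of the pectin methylesterase inhibitor superfamily, was counted 11 and 0 times against 116 and 21. AT5G63180, a pectin lyase-like gene, was counted 10 and 0 times against 79 and 14. BXL3, a beta-xylosidase, was counted 147 and 81 times against 1946 and 133. THI2.1, a thionin of jasmonate-linked defence, was counted 854 and 1509 times against 7289 and 2989, a log2 fold change of 2.16 (SE 0.515). The others were the lectin gene JAL23 (79 and 376 against 1303 and 608), the iron transporter gene IRT1 (31 and 15 against 207 and 35), AT4G12870 of the thiol reductase family (192 and 73 against 772 and 232), AT1G30795 and MIF2. MIF2, a mini zinc finger gene, was counted 0 times in both wild type libraries and 13 and 16 times in spl, at least 5.25-fold higher on the same floor. In all 15 models the genotypes did not overlap in TMM-scaled CPM, and the fold changes within both replicates had the same sign. The fit that picked them favours such agreement, so it is no separate support. BXL3 missed an overlap only narrowly (46.3 CPM in wild type replicate 1 and 47.0 CPM in spl replicate 2) and overlapped in counts. Over all models 29.7% did not overlap, against 33.3% by chance. Transcripts of pollen also differed between replicates: VGD1, a pollen pectin methylesterase gene, was counted 25 and 140 times in wild type and 170 and 5 times in spl, while SPL was counted 0 times in spl replicate 1. Without spl replicate 1, 2 of the 15 were among the 95 calls of the fit without replicate number, and without spl replicate 2, 9 were among the 25.

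**Figure D1:**
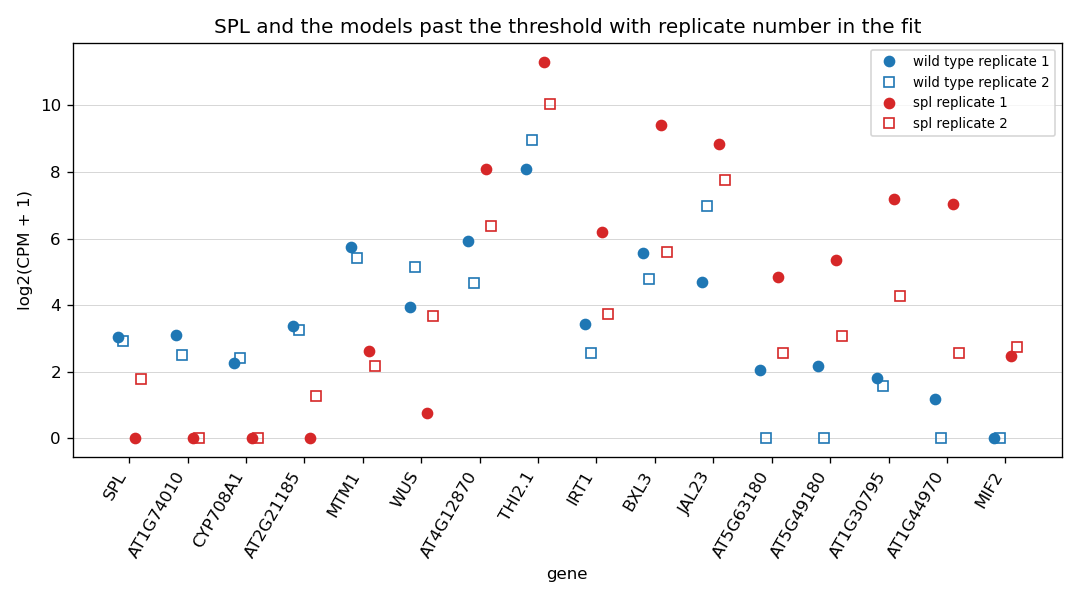
Level of SPL and of the 15 models that passed with replicate number in the fit, as log2(CPM + 1) on the vertical axis, 1 point per library (blue wild type, red spl; filled circles replicate 1, open squares replicate 2). Both spl points lie below both wild type points for SPL and the next 5 genes, MTM1 and WUS among them, and above them for the other 10, several of which are far higher in spl replicate 1 than in spl replicate 2.

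The second question was whether genes of the germ line and of ovule patterning differ as groups. In the germ line specification list, which holds small RNA pathway and other genes that act on the megaspore mother cell, 13 models were tested and 0 passed. Of these, 9 had negative and 4 positive fold changes, with a median log2 fold change of -0.41 (camera adjusted p = 0.574). Its member with the smallest p was ICK5 (KRP7), an inhibitor of cyclin-dependent kinases, at 15.0 ± 0.767 CPM in wild type and 46.3 ± 10.9 CPM in spl (SD, n = 2; log2 fold change 1.62, SE 0.450). AGO9, an Argonaute of the small RNA pathway, was counted 3562 and 2206 times in wild type and 2860 and 1953 times in spl. Among 16 tested meiosis models 0 passed, and 11 had negative fold changes (median -0.30, camera adjusted p = 0.574). The rotation test fry of limma, which asks whether a list moves on balance one way, gave meiosis an adjusted p of 0.139. DMC1, the meiotic recombinase, had the smallest p of that list at 58.1 ± 25.2 CPM in wild type and 28.6 ± 4.94 CPM in spl (SD, n = 2).

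Ovule patterning genes went both ways. Of 19 tested ovule development models 0 passed, with 9 positive and 10 negative fold changes (median -0.04, camera direction up, camera adjusted p = 0.837, fry adjusted p = 0.139). ATS, a KANADI family gene of integument polarity, stood at 56.5 ± 10.1 CPM in wild type and 26.5 ± 8.93 CPM in spl (SD, n = 2; log2 fold change -1.09, SE 0.461). ANT, an integument growth regulator, was counted 2675 and 2359 times in wild type and 2830 and 1618 times in spl. BEL1 and INO, needed for integument identity and growth, had log2 fold changes of 0.54 (SE 0.442) and 0.57 (SE 0.423).

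Hormone lists gave no call. Of 17 cytokinin models 0 passed (median 0.15, camera adjusted p = 0.871); LOG5, an enzyme that activates cytokinins, stood at 230.6 ± 6.82 CPM in wild type and 90.6 ± 18.22 CPM in spl (SD, n = 2; log2 fold change -1.35, SE 0.437). Of 20 auxin models 0 passed (median 0.14, camera adjusted p = 0.727). PIN3, an auxin efflux carrier, had a log2 fold change of 0.88 (SE 0.585), and PIN1 one of -0.11 (SE 0.447). Both signs turned without 1 library: PIN3 to -0.15 without spl replicate 1, and PIN1 to 0.07 without wild type replicate 1 and 0.12 without spl replicate 2. Of 6 tested TCP factors, TOPLESS corepressors and TCP-regulated genes 0 passed (median -0.02, camera adjusted p = 0.668); AS1, a MYB regulator of organ polarity, had a log2 fold change of -0.94 (SE 0.453). Among 24 cell cycle models 0 passed (median 0.10, camera direction down, camera adjusted p = 0.739), and HIK, a kinesin of cytokinesis, had a log2 fold change of -1.15 (SE 0.478). Among 9 flavonoid synthesis models 0 passed, 8 had positive fold changes (median 0.40, camera adjusted p = 0.312), and TT5, chalcone isomerase, was counted 286 and 119 times in wild type and 1203 and 146 times in spl. The flavonoid list passed camera without spl replicate 2 (adjusted p = 0.000115) and without wild type replicate 1 (adjusted p = 0.0125), but with an estimated correlation the adjusted p was 0.874 and 0.889. Without spl replicate 1 the list turned down (median -0.28), and without wild type replicate 2 it stayed up (median 0.40). Within each replicate number the list was up, with a median of 1.14 in replicate 1 and 0.30 in replicate 2. The direction of spl replicate 2 thus depended on which wild type libraries it was set against.

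Markers of neighbouring tissues were followed with the same test. Of 7 mature pollen models 0 passed, with a median of 0.03 and camera direction down (camera adjusted p = 0.668), yet these genes differed widely between replicates, as given above for VGD1. VGDH1, the member with the smallest p, was counted 2 and 16 times in wild type and 10 and 0 times in spl. The pollen list passed camera without spl replicate 1 (median -3.92, adjusted p = 0.000622) and without wild type replicate 1 (median -0.71, adjusted p = 0.000192); with an estimated correlation the adjusted p was 0.989 and 0.889. The direction was up without wild type replicate 2 (median 0.91, camera adjusted p = 0.486) and without spl replicate 2 (median 0.55, camera adjusted p = 0.230). Among 16 photosynthesis models 0 passed (median 0.18, camera adjusted p = 0.727), with LHCA2 at a log2 fold change of -0.58 (SE 0.445). Among 13 carpel and transmitting tract models 0 passed (median 0.15, camera adjusted p = 0.574). JAG, a zinc finger regulator of organ growth, stood at 6.32 ± 0.912 CPM in wild type and 21.3 ± 11.2 CPM in spl (SD, n = 2). Among 11 stress and wounding models 0 passed (median 0.48, camera adjusted p = 0.668; median -0.46 without spl replicate 1 and -0.01 without wild type replicate 2), and HSP70 was counted 5 and 83 times in wild type and 0 and 12 times in spl. Fewer than 5 models could be tested for tapetum and anther genes (4 models, TPD1 at log2 fold change -1.41, SE 0.770), perianth and stamen identity genes (3 models, AP3 at 0.63, SE 0.624) and embryo sac genes (1 model, AGL80 at -0.50, SE 0.725). No member of these 3 lists passed, and AP3 turned to -0.57 without spl replicate 1. Adjusted over the list alone, 0 members of the 15 lists passed, and no list call was made with an estimated correlation (smallest adjusted p = 0.849). With replicate number in the fit, 4 members passed when adjusted over the list alone: WUS and ICK5 of the germ line specification list, JAG of the carpel list and HSP70 of the stress list, of which only WUS also passed over all models.

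**Figure D2:**
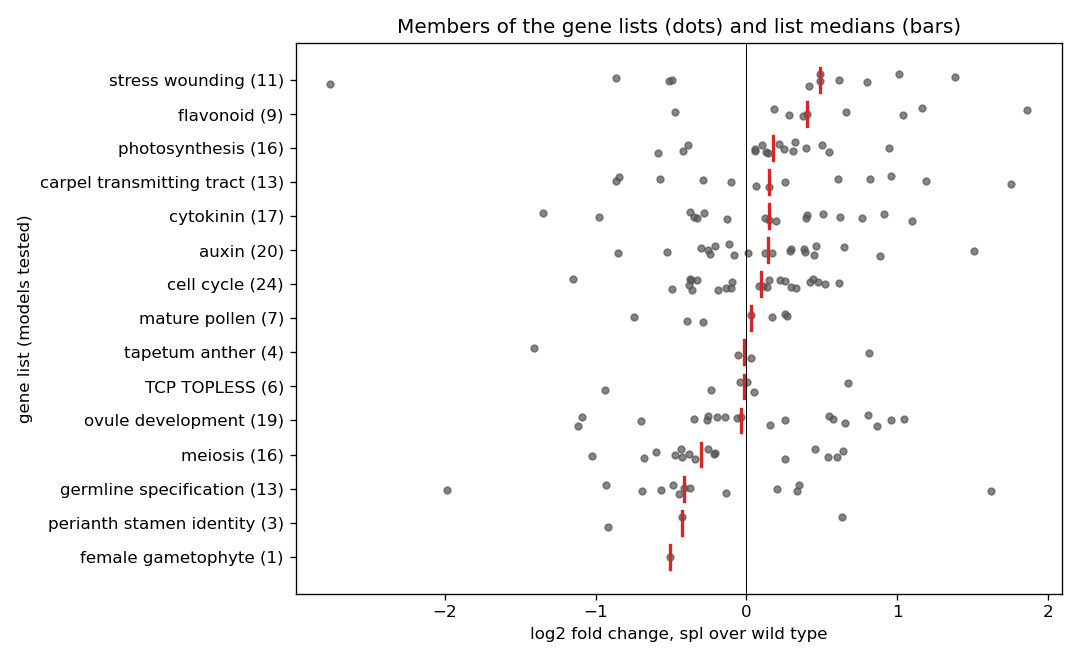
Fitted log2 fold change of spl over wild type on the horizontal axis for each tested member (dots) of the 15 gene lists, with the number of tested models in brackets and a red bar at each list's median. Members of most lists lie on both sides of 0, and list medians run from -0.50 for the single embryo sac gene to 0.48 for stress and wounding; no dot passed the test.

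Gene families defined by their descriptions were tested in the same way. The 219 ribosomal protein models were shifted slightly down in spl as a set, 132 of them with negative fold changes, at a median log2 fold change of -0.09 (camera adjusted p = 0.0196). This call was lost with an estimated correlation (adjusted p = 0.923), without wild type replicate 2 (adjusted p = 0.560) and without spl replicate 1 (adjusted p = 0.370), while the median stayed negative under every scaling tried. AT1G34030, a ribosomal S13/S18 family gene, had the smallest p of its family and was counted 1730 and 1779 times in wild type and 487 and 847 times in spl. The other 11 of the 12 families tested did not pass, with adjusted p from 0.404 to 0.896. The pectin-modifying family (69 models in the main fit) includes pollen genes such as VGD1. It moved in opposite directions when 1 spl library was left out: down without spl replicate 1 (median -0.33) and up without spl replicate 2 (median 0.61). Transposable element genes passed up without spl replicate 1 (median 0.48, camera adjusted p = 0.000164), but their median was -0.33 without spl replicate 2. Without spl replicate 2, lipid transfer genes (median 0.49, camera adjusted p = 0.00171) and peroxidases (median 0.38, camera adjusted p = 0.0127) passed up, with medians of -0.46 and -0.33 without spl replicate 1. Heat shock genes passed with camera direction down without wild type replicate 1 (median 0.01, camera adjusted p = 0.0359). With an estimated correlation none of these calls held (smallest adjusted p = 0.568). Among 24 peroxidase models only AT1G44970 passed when adjusted over the list alone (adjusted p = 0.0292 with edgeR); it was the single such member in the 16 families. With replicate number in the fit there were 8 such members, 4 cytochrome P450 genes (CYP708A1, CYP76C8P, BAS1 and CYP71B7), the pectin-modifying AT5G49180 and AT5G63180, HSP70 and AT1G44970. AT1G09200, a histone H3 gene, stood at 604.8 ± 38.4 CPM in wild type and 1516 ± 51.2 CPM in spl (SD, n = 2; log2 fold change 1.33, SE 0.416), and it did not pass over all models. CYP76C8P, annotated as a cytochrome P450 pseudogene that overlaps another gene, stood at 34.0 ± 2.13 CPM against 127.6 ± 20.3 CPM, and LRR XI-23, a receptor-like kinase, at 14.1 ± 0.182 CPM against 31.2 ± 1.78 CPM. The smallest-p members of the other families, in log2 fold change, were the transposable element gene AT1G47860 (1.58, SE 0.511), the F-box gene AT1G13780 (1.28, SE 0.558), the lipid transfer gene AT1G48750 (1.26, SE 0.712), SHP1 of the MADS family (0.96, SE 0.606), the SAUR-like AT4G38860 (0.90, SE 0.504), the defensin-like LCR68 (0.85, SE 0.456), EXLA2 of the expansins (-0.93, SE 0.459) and the oleosin gene AT3G01570 (-0.47, SE 0.634). Of these, AT1G48750 turned to -0.63 without spl replicate 1. HSP70, JAG and AT5G49180, given above, had the smallest p of the heat shock, C2H2 zinc finger and pectin-modifying families. With simulated counts at the common spread of these libraries, 89.4% of 66 genes changed 8-fold were called. For 4-fold and 2-fold changes the shares were 38.8% of 67 and 1.49% of 67 genes. Differences of 2-fold were thus mostly not detectable at this spread with 2 libraries per genotype. At the same depth and 10% of the dispersion, 73.1% of 67 genes changed 2-fold were called. Every simulated gene had the same spread in both genotypes, without the gap between the spl replicates, so detection in these libraries can be lower. MTM1, at a log2 fold change of -3.41, did not pass the planned comparison (edgeR adjusted p = 0.588).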

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

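The test of copy numbers in this part was chosen after the tag statistics had been seen. Tags that matched no transcript or genome position lie outside the main measurement and were more frequent in both spl libraries, 5.32% and 5.68% of clean tags in replicates 1 and 2, than in wild type, 4.00% and 3.04%. Sense tags with 1 mismatch, which are part of the counts compared, ordered the genotypes alike, at 1.17% and 1.25% in spl and 1.005% and 0.850% in wild type. The unmatched tags are a signal above the wild type libraries in data that no comparison used, and with 2 libraries per genotype the difference was not tested.

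Sequencing errors scattered over abundant tags would give many tags of low copy number. Yet 68.8% of the mean excess of unmatched tags lay in tags with more than 100 copies. This argues against scattered errors as the main source of the excess. Errors that recur in a very abundant tag could exceed 100 copies themselves, so the cut cannot decide on them. The higher share of tags with 1 mismatch in both spl libraries would go with more errors there. Sequence of another accession across the genome of the spl line was argued against at the sites that could be compared. At 14317 tag sites with at least 20 copies in both genotypes, 0.00698% (1 site) had a main spl tag that made up under 10% of the wild type copies. A site whose spl tag lost its CATG or held more than 1 mismatch could not enter. The share also cannot exclude a short segment of other sequence. RNA or DNA from outside the reference stays open for the excess of 1.98% of clean tags, since the sequences of the unmatched tags were not used here. A change in transcripts brought by the genotype itself also stays open and was not tested.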

How the results depend on the processing

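The edgeR comparison called 0 models under DESeq2 size factors, library totals, upper quartile scaling, either low-count setting, robust dispersion, no organellar genes and the log2 threshold, as did limma-trend. The DESeq2 test called 2 models, 1 higher and 1 lower. The replicate numbers are not said to mark a shared batch, and deviations from the genotype means had a correlation of 0.232 between same-numbered libraries. With the replicate block 15 models were called, 10 higher and 5 lower. Leaving out each library gave 4 to 95 calls, 4 to 47 higher and 0 to 48 lower; a genotype with 1 library left is assumed to vary like the other, and the cause was not tested.

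After seeing the data, these were added: clean tag totals as library sizes and counts summed per locus (0 calls each), and variants of the block. With the block, DESeq2 called 3 (2 higher, 1 lower), limma-trend 21 (13 higher, 8 lower), robust dispersion 15 (11 higher, 4 lower), DESeq2 size factors 16 (11 higher, 5 lower) and no low-count filter 12 (9 higher, 3 lower). Of these calls 3, 12, 14, 15 and 9 were among the 15.

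SPL kept a negative log2 fold change in all fits, from -7.41 without spl replicate 2 to -1.48 without spl replicate 1, and never passed. List tests called 0 lists except without single libraries (0 to 2). Family tests called 1, the ribosomal proteins, and 0 with an estimated correlation or fry, with or without the block; leaving out libraries gave 0 to 4. Without 1 library the median changed sign for 8 of the 12 lists and 10 of the 12 families tested. Of the genes named by the rule or called with the block, 6 changed sign without 1 library: PIN3 (-0.15), TT5 (-0.34), AP3 (-0.57) and AT1G48750 (-0.63) without spl replicate 1, VGDH1 (0.22) without spl replicate 2, and HSP70 (0.39) without wild type replicate 2. At the other end of their leave-one-out ranges stood 1.44, 2.65, 1.24 and 2.01 without spl replicate 2, -6.17 for VGDH1 without spl replicate 1 and -8.45 for HSP70 without spl replicate 2; the last 2, like -7.41 for SPL, are fits against a library at 0 and no bounds. Of genes named outside the 15, TT5 passed without spl replicate 2 (adjusted p = 0.0274). Without spl replicate 1 these passed: ICK5 (0.0282) and CYP76C8P (0.00535), higher, and the pollen genes VGD1 (0.00562), AT3G01270 (0.000165), PGA4 (0.00212), AT5G45880 (0.000150) and BCP1 (0.0444), lower. Of 14 genes named besides, all but BEL1 and INO changed sign, VGD1 from -3.92 without spl replicate 1 to 1.89 without wild type replicate 2. Of the 6 genes given first, PIN3 (1.09 and 0.35), TT5 (2.21 and 0.38) and HSP70 (-1.74 and -2.52) had the same sign within replicates 1 and 2. AP3 (1.05 and -0.32), AT1G48750 (1.83 and -0.37) and VGDH1 (1.67 and -3.15) did not. The causes of the sign changes and calls were not tested. The planned tests of antisense tags and of all tags per gene were not run, because the tables used here count unambiguous sense tags only.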

Other observations

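In this part the tests on tapetum genes and on tag GC content were chosen after the results they bear on had been seen. Genes of late pollen followed neither genotype nor replicate number. Of 29 late pollen genes outside the mature pollen list, 18 models had at least 10 counts; all 18 were higher in wild type replicate 2 than in replicate 1, with a median log2 ratio of 1.56, and 17 were higher in spl replicate 1 than in replicate 2, ACT3 being the exception. The pectate lyase gene AT3G01270 was counted 212 and 816 times in wild type and 365 and 37 times in spl, and PGA4, a pollen polygalacturonase, 23 and 64 times against 87 and 0. Summed over the listed genes and scaled by the counted totals alone, levels were 130.0 and 486.2 CPM in wild type and 306.7 and 28.3 CPM in spl. SPL is known to be needed for pollen formation, so these transcripts leave a doubt about the tissue or the label of spl replicate 1. SPL itself ran the way the labels say, counted 0 and 7 times in spl and 23 and 20 times in wild type. Principal component 1, with 52.8% of the variance, set the spl libraries farthest apart, at -54.8 and 53.0. Component 3 set the wild type libraries apart, at -29.0 and 37.2. Component 2, with 26.7%, stood at 34.204 and 20.997 in wild type and -28.409 and -26.792 in spl. With only 4 libraries there are few axes, and how readily such a split arises was not tested, so it is little evidence on the labels. MTM1, AT1G74010 and MIF2 also put the spl libraries together but were picked for their difference, and no test of the labels was made.

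After VGD1, the pollen gene AT5G45880 and BCP1 had shown this pattern, a candidate explanation was RNA of late pollen entering the libraries in different amounts; the other genes went the same way, with a median log2 ratio of spl replicate 1 to spl replicate 2 of 3.23 (quartiles 2.71 and 4.15). Genotype alone was argued against, since the summed level in spl replicate 1 was 2.36 times that of wild type replicate 1 while spl replicate 2 lay below both wild type libraries. Whether anther tissue with its tapetum was dissected along cannot be told: 8 tapetum and sporopollenin models had a median log2 ratio of -0.53, but only 2 of them lay at a mean of 5 to 100 counts, the others being near the floor or high in every library. DRL1, of the sporopollenin pathway, was counted 106 and 361 times in wild type and 178 and 585 times in spl. The labels name no pollen or anther in the samples, and no sort or gate was described.

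Log2 ratios of replicate 1 to replicate 2 in the genotypes had a correlation across models of 0.23, models not being independent. This is nearly the same quantity as the correlation of deviations from the genotype means given above. With a single ratio per genotype, it cannot show that the replicate number is the source of the difference. GC content of the tags was argued against as a shared cause in both genotypes, since its rank correlation with the ratio was 0.0516 in wild type and -0.25 in spl. Harvest in other light or at another time of day was tested with 9 light-induced and 10 darkness- or starvation-induced models. The light set exceeded the dark set by a median log2 ratio of 1.19 in spl, at percentile 98.9 of 10000 random list pairs. In wild type it did so by 0.13, at percentile 66.0, so this explanation stays open. The random lists were drawn from all tested models, unmatched for level, while genes that respond together are not independent. The percentiles can thus overstate how unusual the differences are. RUP1, a light-induced repressor of UV-B signalling, was counted 60 and 18 times in wild type and 45 and 10 times in spl. ELIP2, an early light-induced protein gene, was counted 58 and 18 times against 53 and 9. These are strong cases: BBX21 was counted 36 and 31 times in wild type and 31 and 62 times in spl. Of the 9 light-induced models, 8 in wild type and 7 in spl were higher in replicate 1. Of the 10 darkness- or starvation-induced models, 7 and 5 were.

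MTM1, the model with the smallest p, starts 220.9 kb from the end of SPL on chromosome 4. Its site nearest the 3′ end held 164 and 125 of its 166 and 125 counts in wild type replicates 1 and 2. In spl replicates 1 and 2 that site held 15 and 3 of 15 and 10 counts, so most copies in spl replicate 2 lay elsewhere. The cause of this shift was not tested. Of 264 tested models within 1 Mb of SPL, 8 had an unadjusted edgeR p under 0.05, or 3.03%, against 2.62% of all tested models.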
